A study of Mus musculus with 24 samples.

How the data were processed

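RNA was measured in GFP-positive cells sorted from the hippocampus of adult C57BL/6 mice. In these animals a tamoxifen-inducible Cre driven from Hes5, a Notch target gene that marks neural stem cells, switched on a GFP reporter, and in the conditional knockout (CKO) animals it also recombined a floxed Notch2 gene. Wild-type (WT) animals carried the driver and the reporter with intact Notch2. Tamoxifen was given for 5 days and cells were collected after 1 day of chase. Cells of several animals were pooled per sample, per the labels' protocols. Full-length cDNA was made with Smart-Seq2 and libraries with Nextera XT, a combination that does not mark the strand of a transcript.

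The deposited tables held raw read counts per gene, 1 table for each of 24 sequencing runs. Per the submitters' processing notes, the authors used Bowtie2 and HTSeq with the mouse build GRCm38. Their versions, the gene annotation and the counting settings were not given in the sources used here. Each table listed 48321 gene symbols and 5 summary lines that name no gene. The summary lines were kept out of library sizes and tests. Reads outside annotated genes made up 16.0% to 35.3% of all reads per pool, unaligned reads 11.2% to 21.7%, and reads in overlapping genes that were set aside as ambiguous 2.51% to 3.43%. The lines for reads with several alignments and for low alignment quality held 0 reads in every table, so reads from near-identical genes may have been placed on any copy. Counts of paralogs, pseudogenes and members of gene families, such as the Serpina3, H2, S100a and haemoglobin genes and the ribosomal protein genes, are therefore uncertain. Overlapping and antisense genes cannot be told apart where the counting ignored strand.

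The labels placed the 24 runs in 6 pools, 3 of each genotype. Each pool had 2 libraries, and each library was run on 2 lanes, 4 and 5. Read counts of the lanes of a library differed by no more than sampling noise (chi-square divided by its degrees of freedom 0.986 to 1.01 over 12 libraries, smallest p = 0.149), so lanes were summed. The libraries of a pool differed far more (70.7 to 351), but they carry the same pool label and were summed as repeat measurements of 1 pool. The unit of replication was the pool, with n = 3 per genotype. The labels state that pools of animals were used but not that no animal was shared between pools, so the p-values measure the spread between these pools. The description of each sample also carries a tag of 20K, 12K and 2K for WT pools 1 to 3 and 19K, 4K and 9K for CKO pools 1 to 3, whose meaning was not given in the sources used here.

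Genotypes were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with genotype as the group, which left 21477, libraries were scaled by TMM, and a quasi-likelihood F test with robust dispersion estimates was run on 3 against 3 pools with no further covariate. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Normalised levels are CPM, read counts scaled to the TMM-adjusted library size, and log2 fold changes are CKO over WT with standard errors (SE) from the same fit. Single values were also compared with an exact two-sided permutation test of log2 CPM over the splits of the pools, which cannot give a p under 0.1 with 3 against 3. Expression of 31 gene lists, 20 of pathways and cell states and 11 of cell type markers, was compared with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 31 lists. The level of a list is the mean log2 CPM of its members.

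The lists, the tests and the rule for the genes named in the text were fixed before the data were examined. By that rule the text names Notch2, 19 fixed genes of Notch signalling, stem cells, the cell cycle and neurogenesis, the members with the smallest p of each list, and genes past the adjusted threshold. Since no gene passed it, the rule gave for each direction the 6 genes with the smallest unadjusted p among those with a mean log2 CPM of at least 1, with no overlap between the pools of the genotypes, and with a symbol that is not a clone, pseudogene or predicted model. The values of those genes are given without calling them changed. Some genes that the rule names are not reported here. Positions are those of GENCODE M21 on GRCm38, matched by symbol for 96.2% of the tested genes.

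Depth was 40366579 to 53984963 reads in genes per pool, and 1 read corresponded to 0.0175 to 0.0265 CPM at the TMM-adjusted library sizes. Reads carry no molecular identifiers, so depth limits counting error only. The spread between pools was larger, with a common biological coefficient of variation of 0.725. The edgeR and DESeq2 steps were tested on simulated data made with the means, dispersions and library sizes of these pools. Of 21476 genes, 200 were changed by known folds, and the glycolysis list was raised 2-fold besides. Counts were drawn independently for each gene. At the dispersion of these pools, edgeR recovered 2% of the genes changed 2-fold, 10% of those changed 4-fold, 48% of those changed 8-fold and 66% of those changed 16-fold, 50 genes at each size, with 2 false calls. DESeq2 recovered 12%, 58%, 86% and 88% of them with 153 false calls.

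Alternatives were other scalings (RLE size factors, upper quartile, mitochondrially encoded genes left out), DESeq2 1.42.0, limma-voom with quality weights, no filter, a CPM over 1 in 3 pools, the replicate number as a block, each pool left out in turn, library 1 or 2 alone, lane 4 or 5 alone, the 12 libraries as replicates with and without a within-pool correlation, the log2 of the description tag as a covariate, and, for lists, an estimated inter-gene correlation and fry. A covariate of Y-linked expression and the joint use of DESeq2 with a left-out pool were added after seeing the data.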

Results

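The transcriptomes of sorted GFP-positive hippocampal cells of WT mice and of mice with a conditional deletion of Notch2, a Notch receptor, were compared. There were 6 pools, 3 labelled WT and 3 labelled Notch2 CKO. Oligodendrocyte markers were also abundant in them (below), so the values describe the sorted cells as a whole and not stem cells alone. Reads in genes numbered 52682485, 42153213 and 40366579 in WT pools 1, 2 and 3. They numbered 53984963, 41810239 and 52303947 in CKO pools 1, 2 and 3. Between 26502 and 38187 gene symbols had at least 1 read in a pool. The comparison asked which genes respond in these cells when Notch2 is deleted.

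Notch2 itself (chromosome 3, 98013527 to 98150361, plus strand, GRCm38) stood at 183 ± 107 CPM in WT and 101 ± 30.8 CPM in CKO pools (mean ± SD, n = 3 pools each). Single WT pools had 99.3, 146 and 303 CPM, and single CKO pools 65.3, 116 and 121 CPM, so that the genotypes overlapped. The log2 fold change was -0.86 (SE 0.45) and did not pass the test (edgeR adjusted p = 0.790, exact permutation p = 0.3, where 0.1 is the smallest possible). It was -0.57 in library 1 and -1.14 in library 2 of the pools. The value rested on WT pool 3, without which it was -0.29. The floxed exons were not given in the labels, and a gene-level count includes reads from exons that remain after recombination, so the count measures deletion only in part. The gene also overlaps Gm42819 and Gm42820, whose reads cannot always be told from its own. Gm42819, picked out after the results were seen, had a log2 fold change of 3.78 (SE 0.84, edgeR adjusted p = 0.790, unadjusted p = 0.00253), opposite in sign to Notch2.

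Notch1, the paralogous receptor, was at similar levels in both genotypes (106 ± 6.43 CPM in WT, 105 ± 12.9 in CKO, log2 fold change -0.01, SE 0.21), and so was Hes5, the Notch target whose promoter drove the Cre (379 ± 133 and 382 ± 19.7 CPM, log2 fold change 0.01, SE 0.29). By library, however, Notch1 was at -0.56 in library 1 and 0.22 in library 2. Hes1 and Hey1, further effectors of Notch signalling, had log2 fold changes of -0.26 (SE 0.38) and -0.39 (SE 0.33). They were at -0.48 and 0.32 in library 1 and at 0.10 and -0.75 in library 2. Hes1 was at 0.01 without WT pool 1 and Hey1 at -0.16 without WT pool 3. Of the 4 Id genes, which encode inhibitors of proneural transcription factors, Id4 was lower in all 3 CKO pools than in any WT pool. Id4 (chromosome 13, 48261228 to 48266026, overlapping the antisense gene A330033J07Rik) stood at 71.3 ± 12.2 CPM in WT and 45.8 ± 1.44 CPM in CKO pools (n = 3 each), a log2 fold change of -0.64 (SE 0.24) that did not pass after adjustment (edgeR adjusted p = 0.790, unadjusted p = 0.0337, exact permutation p = 0.1). Within library 1 it was -0.92 and within library 2 -0.32. Id1, Id2 and Id3 had log2 fold changes of -0.45, -0.26 and -0.41, each with overlapping pools, and those of Id1 and Id3 were negative in library 1 and positive in library 2. Without WT pool 1 that of Id1 was 0.14.

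**Figure D1:**
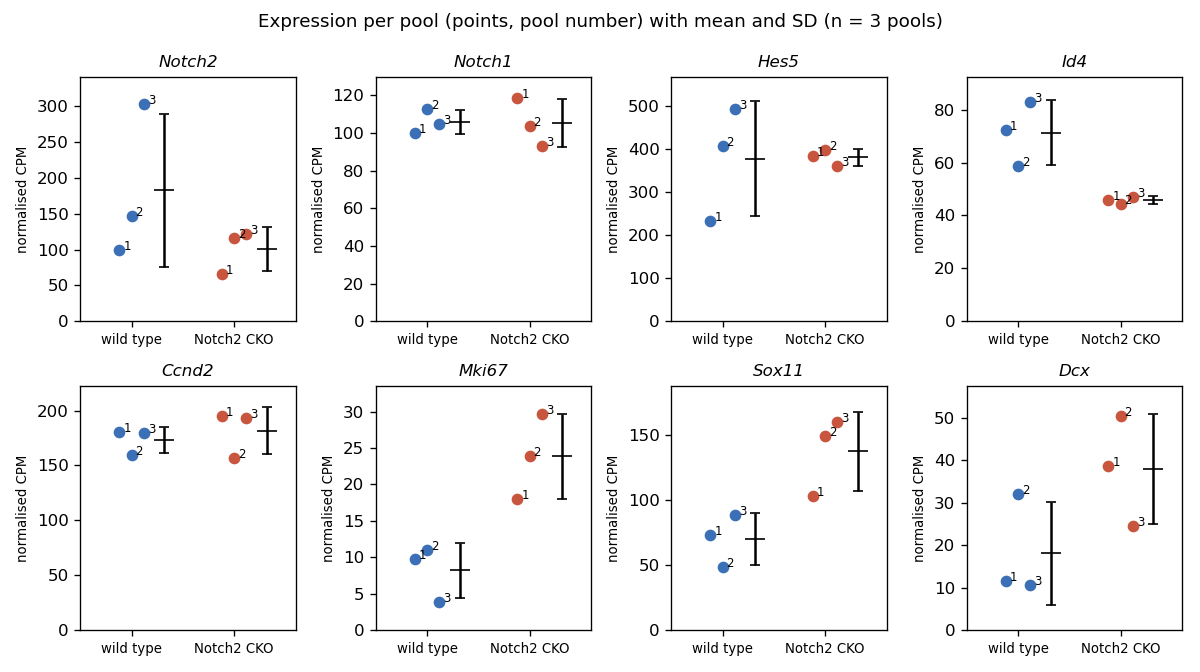
Normalised CPM (y axis, from 0) of 8 genes in each WT pool (blue) and Notch2 CKO pool (red), with the pool number beside each point and the mean ± SD of 3 pools in black. Id4 was below the WT pools and Mki67 and Sox11 above them in all 3 CKO pools, while the pools overlapped for the other 5 genes.

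Among proliferation and lineage genes, Mki67, a marker of cycling cells (chromosome 7, 135689784 to 135716361), was higher in each CKO pool than in any WT pool, at 23.9 ± 5.82 against 8.24 ± 3.76 CPM (log2 fold change 1.54, SE 0.51, n = 3 each, edgeR adjusted p = 0.790, unadjusted p = 0.0188). Its log2 fold change was 1.14 in library 1 and 1.54 in library 2. Ccnd2, a cyclin, stood at 173 ± 11.9 against 182 ± 21.6 CPM in WT and CKO pools, with log2 fold changes of -0.56 in library 1 and 0.63 in library 2. Ccnd1 and the cell cycle inhibitor Cdkn1b had log2 fold changes of -0.38 (SE 0.41) and 0.51 (SE 0.34), and Cdkn1b was higher in each CKO pool than in any WT pool. Without CKO pool 2, Cdkn1b was at 0.31. Of the stem cell genes, Gfap, Sox2 and Hopx had 0.52 (SE 0.28), -0.20 (SE 0.35) and -0.53 (SE 0.31), and Hopx was lower in each CKO pool than in any WT pool. Eomes, Neurod1 and Dcx, expressed along the path from progenitor to neuroblast, had 0.63 (SE 0.73), -0.65 (SE 0.48) and 1.07 (SE 0.54). Without WT pool 3, Ccnd1, Sox2 and Neurod1 were at 0.12, 0.10 and -0.23. Gfap was at 0.22 without CKO pool 3 and Dcx at 1.82 without WT pool 2, while Eomes was at 1.74, 0.32 and 0.32 without WT pools 1, 2 and 3. None of these genes passed the adjusted threshold.

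Across all 21477 genes tested, 0 passed an adjusted p under 0.05 in edgeR, with a smallest adjusted p of 0.790. At an unadjusted p under 0.05 there were 1269 genes (5.91%), 647 higher and 622 lower in CKO. The pools of the genotypes did not overlap for 1647 genes that were higher and 1755 that were lower in CKO, 15.8% of genes where 10% are given by chance. DESeq2 called 129 genes, 84 higher and 45 lower. On simulated pools of this spread, with 200 genes and the glycolysis list changed, it made 153 false calls. That number need not hold where fewer genes change or where genes move together. On the other splits of the 6 pools into 3 and 3 DESeq2 called 24 to 127 genes. The limma-voom fit with quality weights called 0. With the 12 libraries as replicates, both fits called 3 genes. The fit that took them as independent counts each pool repeatedly. The other allowed for a within-pool correlation, which it estimated at only 0.0265, so it too treated the libraries as almost independent.

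The 6 genes with the smallest p among those higher in CKO were Serpina3m, Cep85l, Serpina3n, Fanci, Rnd3 and Lrrc59. Serpina3n (chromosome 12, 104406729 to 104414329), a serine protease inhibitor of reactive astrocytes, stood at 111 ± 25.0 CPM in WT and 270 ± 18.6 CPM in CKO pools (log2 fold change 1.28, SE 0.23). Its neighbour Serpina3m (104338486 to 104394257) stood at 0.688 ± 0.291 and 11.8 ± 2.25 CPM (4.09, SE 0.63). Both belong to a family of close copies that can share reads. Fanci, of the Fanconi anaemia DNA repair pathway, stood at 0.996 ± 0.530 and 11.4 ± 2.98 CPM, and Rnd3, an atypical GTPase, at 10.8 ± 2.40 and 40.8 ± 11.1 CPM. The log2 fold change of Rnd3 was 3.30 in library 1 and 0.98 in library 2. Cep85l, a centrosomal protein, and Lrrc59, a protein of the endoplasmic reticulum, had log2 fold changes of 1.85 (SE 0.33) and 1.48 (SE 0.32), which were 0.59 and 3.03 in library 1 and 2.20 and 0.34 in library 2.

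The 6 with the smallest p among those lower in CKO were Riiad1, Scnm1, Ccl9, S100a3, Perp and Zfp949. Scnm1 (chromosome 3, 95129536 to 95134011), a splicing factor, stood at 79.5 ± 20.3 CPM in WT and 24.3 ± 2.45 CPM in CKO pools (log2 fold change -1.71, SE 0.29). Zfp949, a zinc finger gene, stood at 92.5 ± 53.8 and 17.4 ± 4.50 CPM. S100a3 (chromosome 3, 90560578 to 90602702), a calcium-binding protein, stood at 29.9 ± 4.49 and 4.43 ± 2.24 CPM, and Riiad1 (chromosome 3, 94464983 to 94480341) at 12 ± 3.53 and 1.12 ± 0.218 CPM. Thus 3 of these 6 genes lay on chromosome 3 within 10 Mb of Notch2. Ccl9, a chemokine, and Perp, a p53 target, were at 3.87 ± 2.12 and 5.02 ± 3.29 CPM in WT and at 0.131 ± 0.0116 and 0.0853 ± 0.0841 CPM in CKO pools, where 3 reads are 0.0526 to 0.0673 CPM. In WT pools 1 and 3 the reads of Ccl9 and Perp came mostly from a single library. Ccl9 had 6 and 178 reads in libraries 1 and 2 of WT pool 1, and 4 and 226 in WT pool 3. Perp had 5 and 156, and 324 and 9, in the same order. Neither gene was tested in library 1 alone. S100a3 had 26 and 1164 reads in libraries 1 and 2 of WT pool 3. All 12 genes had an edgeR adjusted p of 0.790 and passed in DESeq2.

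**Figure D2:**
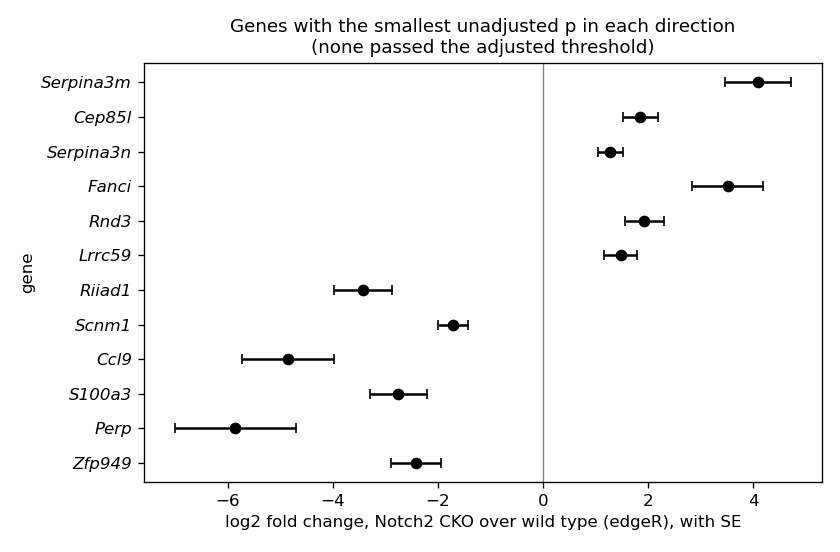
Log2 fold change of CKO over WT (x axis) with its SE for the 6 genes of each direction with the smallest unadjusted p (y axis), from edgeR on 3 against 3 pools. Values ran from -5.86 for Perp to 4.09 for Serpina3m, and none passed the adjusted threshold.

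By camera at its preset correlation, 2 of the 31 lists were lower in CKO and 0 were higher. The list of nuclear genes of oxidative phosphorylation was lower, with 75 of 77 members below 0 and a mean log2 fold change of -0.58 (camera adjusted p = 1.47e-11), and the cytosolic ribosomal protein genes likewise, with 78 of 80 below 0 and a mean of -0.57 (camera adjusted p = 4.79e-09). With an estimated inter-gene correlation neither was called (unadjusted p = 0.271 and p = 0.334, smallest adjusted p = 0.994 over the 31 lists), and fry called 0 lists (smallest adjusted p = 0.437). In each of the 31 lists, 0 members passed edgeR over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 14 members of the oxidative phosphorylation list and 4 of the ribosomal list, all lower. Ndufv3, a subunit of respiratory complex I, stood at 186 ± 36.4 CPM in WT and 108 ± 12.8 CPM in CKO pools, and Atp5j2, of the ATP synthase, at 139 ± 38.6 and 78.1 ± 12.5. Rpl13 stood at 110 ± 32.1 and 56.0 ± 13.1, and Rpl7a at 24 ± 9.34 and 11.9 ± 1.31 CPM.

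WT pool 1 had the highest level of both lists, and also of the excitatory neuron, interneuron, endothelial, pericyte and red blood cell markers. Mean log2 CPM of the oxidative phosphorylation list was 8.10, 7.22 and 7.23 in the WT pools and 6.89, 6.98 and 7.14 in the CKO pools, and that of the ribosomal list 5.61, 4.48 and 4.54 against 4.32, 4.45 and 4.46. Without WT pool 1 the ribosomal list was not called (mean log2 fold change -0.10, camera adjusted p = 0.170), while that of oxidative phosphorylation was still called at a smaller mean of -0.20 (camera adjusted p = 0.00123, p = 0.347 with an estimated correlation). Library 1 had the higher level of both lists in each of the 6 pools, and the genotypes differed by -0.68 log2 units within library 1 and -0.25 within library 2 for oxidative phosphorylation, and by -0.61 and -0.24 for the ribosomal list.

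**Figure D3:**
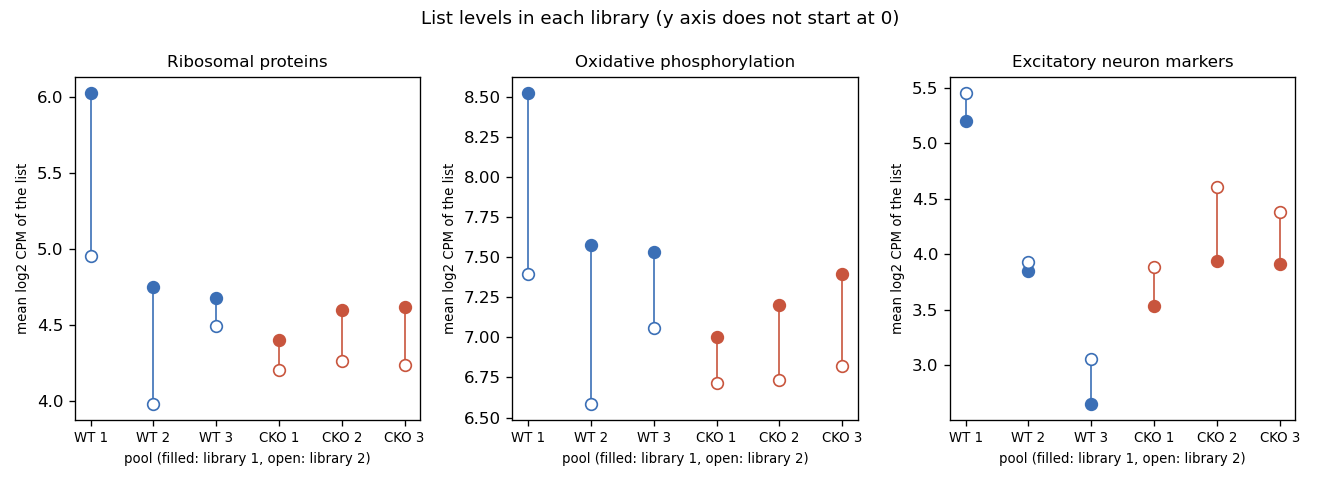
Mean log2 CPM of the members of 3 lists (y axes, not from 0) in library 1 (filled) and library 2 (open) of each WT pool (blue) and CKO pool (red). Within each library WT pool 1 lay highest for all 3 lists, with 8.52 and 7.40 for oxidative phosphorylation in its libraries 1 and 2.

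Genes of the cell cycle and DNA replication did not pass as a list. Of 44 members, 24 were above 0, 7 had an unadjusted p under 0.05 upwards and 1 downwards, and the mean log2 fold change was 0.31 (camera adjusted p = 0.157, unadjusted p = 0.0151, p = 0.281 with an estimated correlation). Ccne1, the cyclin of S phase entry, stood at 1.52 ± 0.685 CPM in WT and 7.58 ± 0.416 CPM in CKO pools, and Bub1, of the spindle checkpoint, stood at 1.54 ± 1.16 and 9.17 ± 2.30 CPM. Their log2 fold changes differed between libraries, at 0.55 and 4.61 in library 1 and 3.59 and 1.74 in library 2. At the preset correlation the list passed when WT pool 1, WT pool 3 or CKO pool 2 was left out (camera adjusted p = 0.0119, 0.029 and 0.0187) and with library 1 alone (0.0222). No estimated correlation is given for these settings, and the list passed in 4 of 18 alternatives. In the stem cell activation list, 11 of 18 members were above 0 (mean 0.23, camera adjusted p = 0.505), among them Sox11 at 70.2 ± 20.1 against 138 ± 30.3 CPM and Egfr at 24.7 ± 12.3 against 48.8 ± 11.8 CPM. The log2 fold change of Sox11 was 1.504 in library 1 and 0.42 in library 2, and that of Egfr was 0.98 with all pools and 1.53 without WT pool 2. Cell cycle inhibitors had 11 of 16 members above 0 (mean 0.21, adjusted p = 0.468), with Cdkn2d at 88.9 ± 28.5 against 52.6 ± 12.1 CPM and Btg2 at 36.6 ± 11.7 against 60.1 ± 20.6 CPM.

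Lists of Notch signalling did not pass. Of 28 receptor, ligand and machinery genes, 18 were above 0 (mean 0.10, camera adjusted p = 0.468), with Adam10, the protease that sheds the receptor ectodomain, at 56.3 ± 19.1 against 109 ± 25.8 CPM and the glycosyltransferase Rfng at 28.4 ± 8.04 against 68.7 ± 6.24 CPM. The Rfng difference came from library 2 (log2 fold change 2.48), and in library 1 it had the opposite sign (-0.59). The 15 Notch target genes had a mean of 0.11 (adjusted p = 0.981), with Id4 as above and Hey2 at 1.52 ± 0.961 against 7.50 ± 3.61 CPM. The Id and BMP list had a mean of 0.13 and a median of -0.02 over 17 genes (adjusted p = 0.985), with the BMP pseudoreceptor Bambi at 35.0 ± 29.3 against 7.99 ± 2.72 CPM (log2 fold change -3.31 in library 1, -1.21 in library 2 and -1.18 without WT pool 3). The radial glia and quiescence list was even (16 of 30 above 0, mean 0.07, adjusted p = 0.985), with the gap junction gene Gja1 at 3465 ± 1208 against 5633 ± 1407 CPM and the metallothionein Mt2 at 256 ± 76.4 against 171 ± 37.6 CPM. The log2 fold change of Mt2 was -0.58 with all pools and -0.30 without WT pool 1. Intermediate progenitor and neuroblast genes had 14 of 31 members above 0, with a mean of 0.03, a median of -0.04 and a test that pointed up (adjusted p = 0.638).

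Metabolic, stress and other signalling lists did not pass either. Mitochondrially encoded genes had a mean log2 fold change of 0.03 over 13 genes (camera adjusted p = 0.985), with mt-Co3 at -0.32 and mt-Nd4 at 0.20. Fatty acid synthesis (mean 0.10, adjusted p = 0.713) included Scd1, a desaturase, at 0.90 (SE 0.36) and Elovl1 at -0.34. Fatty acid oxidation (mean 0.02, median -0.05, test downwards, adjusted p = 0.985) included Eci1 at -0.80 (SE 0.21) and Cpt2 at 0.66 (SE 0.26), which were -1.10 and 1.74 in library 1 and -0.35 and 0.12 in library 2. Cholesterol synthesis (mean -0.03, adjusted p = 0.981) included Mvd at -0.69 and Hmgcs1 at 0.59. Glycolysis (mean -0.12, adjusted p = 0.468) included Hk2 at 2.80 (SE 1.04) and Slc16a1 at 0.73. Immediate early and dissociation stress genes had a mean of 0.11 (adjusted p = 0.693), with Fosb at 0.304 ± 0.133 against 2.82 ± 1.75 CPM and Atf3 at 0.881 ± 0.954 against 3.50 ± 1.45 CPM. The interferon list had a mean of 0.37 (adjusted p = 0.468), with the class I gene H2-D1 at 250 ± 33.9 against 135 ± 8.66 CPM and Irf7 near the detection limit in WT at 0.0487 ± 0.0495 against 3.19 ± 2.54 CPM. Means of the Wnt, Hedgehog and adhesion lists were 0.07, 0.23 and 0.21 (adjusted p = 0.571, 0.571 and 0.468), with Fzd3 at 1.85 and Lrp5 at -2.03, Gli3 at 0.71 and Smo at -0.75, and Itgb1 at 0.93 and Cd9 at -0.57 on the log2 scale. The value of Lrp5 rested on WT pool 3, at 32.2 CPM against 2.16 to 5.97 in the other pools, and was -0.61 without it. Fzd3 was at 3.72 without WT pool 2. Without WT pool 1, mt-Co3, mt-Nd4, Elovl1 and Cd9 were at 0.02, 0.02, 0.01 and -0.31.

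**Figure D4:**
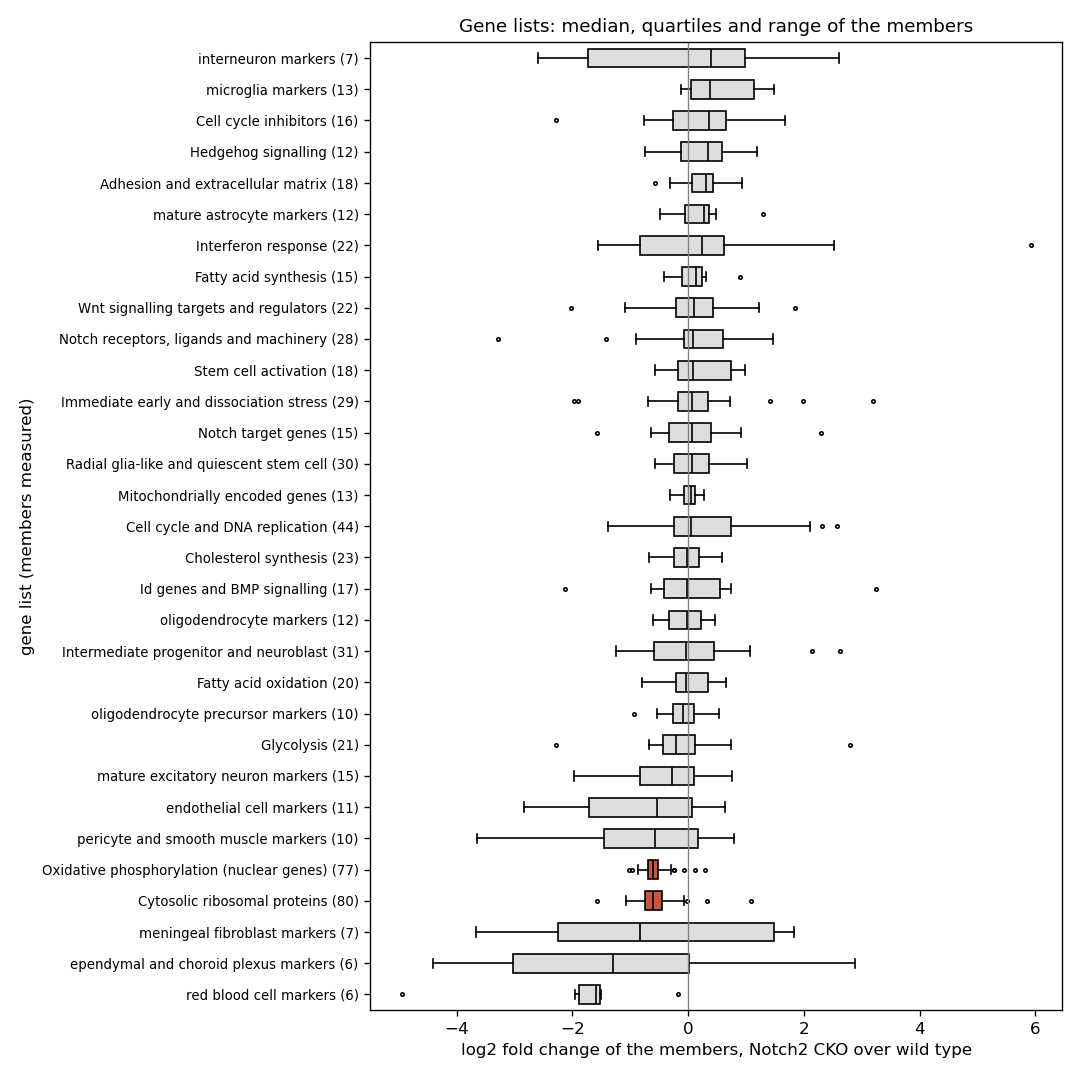
Log2 fold changes of CKO over WT (x axis) of the members of each of the 31 lists (y axis, members measured in brackets), as boxes of median and quartiles with whiskers to 1.5 times the interquartile range and single genes beyond. The 2 lists that the camera test called at its preset correlation are red, with medians of -0.61 and -0.61.

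None of the 11 lists of markers of other cell types passed the camera test. Mature astrocyte markers stood at a mean log2 CPM of 7.56 to 8.42 in the 6 pools and had a mean log2 fold change of 0.22 (camera adjusted p = 0.713), with S100b at -0.49 and Slc6a11 at 0.41. Oligodendrocyte markers were abundant throughout (6.22 to 7.47, mean fold change -0.07, adjusted p = 0.985), with Mbp at -0.58 and Mobp at -0.61. Precursor markers ranged from 6.25 to 7.54 (mean -0.12, adjusted p = 0.574), with C1ql1 at -0.93 and Cspg4 at -0.54, which were -0.54 and -0.24 without CKO pool 3. Microglial markers were highest in CKO pool 3 at 5.65 (mean 0.57, adjusted p = 0.468), with P2ry12 at 1.14 and C1qc at 0.67, which were 0.23 and 0.21 without that pool. Excitatory neuron markers were at 5.53 in WT pool 1 and 3.16 to 4.44 in the other pools (mean -0.38, adjusted p = 0.574), with Olfm1 at -0.87 and Camk2b at -0.81. The mean level of this list was 4.21 ± 1.21 in WT and 4.13 ± 0.339 in CKO pools. Without WT pool 1 the mean log2 fold change of these markers was 0.66, and Olfm1 and Camk2b were at -0.34 and -0.20. Interneuron markers were at 4.11 in WT pool 1 (mean -0.15, median 0.39, test upwards, adjusted p = 0.693), with Gad1 at 0.83 and Npy at -2.14. Npy stood at 51.7 CPM in WT pool 1 and 2.76 to 6.52 CPM in the other pools, so that its value rested on that pool.

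Vascular and blood markers were low and uneven. Endothelial markers were at 3.72 in WT pool 1 and -0.61 in WT pool 3 (mean log2 fold change -0.93, camera adjusted p = 0.985), with Tek at -2.84 and Kdr at -2.64. The mean level of the endothelial list was 1.80 ± 2.21 in WT and 1.84 ± 0.448 in CKO pools. That of the pericyte list was 0.98 ± 1.61 and 0.87 ± 0.633. These levels differed less than the mean fold changes of the members did. Tek rested on WT pool 1 and Kdr on WT pool 3, without which they were 0.43 and -0.28. Pericyte markers were at 2.21 and -0.84 in these pools (mean -0.81, adjusted p = 0.985), with Kcnj8 at -3.65 and Vtn at -1.34, which were -0.84 and -0.09 without WT pool 1. Ependymal and choroid plexus markers (6 of 12 measured, mean -1.22, adjusted p = 0.638) included Kl at 2.88 and Dynlrb2 at -3.42, the latter -1.95 without WT pool 1. Meningeal fibroblast markers (mean -0.60, median -0.82, test upwards, adjusted p = 0.985) included Igfbp2 at 1.35 and Col1a2 at -3.67, the latter -1.26 without WT pool 3. All 6 red blood cell markers were below 0 (mean -1.96, adjusted p = 0.210, p = 0.334 with an estimated correlation), with the beta-globin gene Hbb-bs at 22.4 ± 32.5 against 5.76 ± 6.84 CPM, a log2 fold change of -1.96 that was 0.67 without WT pool 1. At the preset correlation this list passed without CKO pool 3 (camera adjusted p = 0.0015). No estimated correlation is given for that setting, and over all pools it was 0.649.

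Repeat libraries of a pool resembled each other about as much as libraries of different pools did. Across genes, log2 CPM correlated at a median Pearson r of 0.993 between lanes, 0.848 between the libraries of a pool (0.715 to 0.904, 6 pairs), 0.840 between libraries of different pools of a genotype and 0.824 between libraries of different genotypes. The best partner of a library was the other library of its pool for 3 of 12 libraries. Of the 82 genes under the naming rule that could be tested in each library alone, 72 had a fold change of the same sign in both, but most of them were chosen by their p in the sum of both libraries. WT pool 3 stood apart from the other pools, with r of 0.798 to 0.824 to them and 0.715 between its own libraries, and it was separated on the first principal component, which carried 44.0% of the variance. Genes are not independent replicates in these correlations.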

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

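The joint use of DESeq2 with a left-out pool and the Y-linked covariate were chosen after seeing the data. Where edgeR on the 6 pools called 0 genes (1269 at an unadjusted p under 0.05), DESeq2 called 129, and 176 without WT pool 1 or 318 without WT pool 3. The 12 libraries called 3 genes as if independent and 3 with duplicateCorrelation. Every other edgeR or limma setting called 0, and leaving out 1 pool at a time gave 0 with 706 to 2396 genes at an unadjusted p under 0.05. The 10 splits of the 6 pools are too few for a share under 0.05. The real split was the 1 of 10 with the most genes at an unadjusted p under 0.05 (1269, highest other 841) and the 1 of 10 with the most DESeq2 calls (129, highest other 127). By edgeR's adjusted p all 10 splits gave 0. By camera's preset correlation the real split called 2 lists and the highest other 10, and all 10 splits called as many as the real split or more. The pools shared only a number, with correlations of the deviations of same-numbered pools of 0.0559, 0.0218 and -0.0280, and the replicate block gave 0 genes (889 at an unadjusted p under 0.05), a Notch2 log2 fold change of -0.75 and 2 lists.

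Notch2 ranged from -1.15 to -0.29 over 22 alternatives, the higher value without WT pool 3. Of 1938 values of named genes under the alternatives, 18 passed the threshold and 40 had the opposite sign, of which 1, Rfng at -0.59 in library 1, was more than 1 SE from 0 in both fits. Of 557 list values, 6 passed newly, 5 no longer passed and 58 means had the opposite sign, among them the excitatory neuron markers without WT pool 1. With an estimated correlation 0 lists were called and with fry 0, at unchanged means of -0.57 for the ribosomal and -0.58 for the oxidative phosphorylation list, since these settings alter the test alone. Leaving out 1 pool gave ribosomal means of -0.74 to -0.10, cell cycle means of 0.21 to 0.56, red blood cell markers at -3.49 to -0.071 and excitatory neuron markers at -0.68 to 0.66. At the preset correlation the cell cycle list passed at 0.62 in library 1 and the microglial markers at 0.83 in library 2. The cause of these shifts was not tested. Lanes of a library differed by no more than sampling noise, while the chi-square of libraries of a pool was 70.7 to 351 times its degrees of freedom, so more reads of the same libraries would not remove that spread.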

Other observations

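The Serpina3 and H2 genes as groups, the tests of windows near Notch2, those of WT pool 1 as the cause and the genes of the last paragraph were chosen after the results were seen. The Serpina3 genes, serine protease inhibitors in a cluster on chromosome 12, were all above 0 in CKO, 9 of 9 tested, under each scaling, and 5 had an unadjusted edgeR p under 0.05. After Serpina3m and Serpina3n the smallest p were those of Serpina3f (log2 fold change 2.55, SE 0.64), Serpina3c (2.70, SE 0.75) and Serpina3h (3.44, SE 1.21). The mean log2 CPM of these 3 was low, at 1.53, 0.54 and -1.50, against 7.57 for Serpina3n. For 6 of the 9 the pools of the genotypes did not overlap, where chance gives 10% and all tested genes had 15.8%. Their close sequence lets reads of 1 member count for others, so they are not 9 independent measurements.

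The H2 genes were grouped by symbol, and most of them encode major histocompatibility complex proteins. Of 24 tested, 15 were below 0 and 9 above, under each scaling. At an unadjusted edgeR p under 0.05 there were 6 lower and 1 higher, and 0 passed after adjustment. The pools of the genotypes did not overlap for 11 that were lower and 4 that were higher, where all tested genes had 15.8%. Reads of 1 member can count for others here too. H2-D1 had a log2 fold change of -0.89 (SE 0.20), H2-Q10 -2.33 (SE 0.52) and H2-M2 -6.004 (SE 1.15), against 5.94 (SE 1.503) for H2-DMb1 and 0.13 (SE 0.32) for H2-K1. Of these, H2-M2 and H2-DMb1 had low counts, with a mean log2 CPM of -0.85 and 0.21. H2-D1, H2-Q10 and H2-K1 were at 7.59, 2.56 and 6.90.

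The ribosomal protein and oxidative phosphorylation lists were lower in CKO by camera at its preset correlation, but were not called with an estimated correlation (p = 0.334 and p = 0.271). Other genes matched on length and expression had a median log2 fold change of -0.38, between the lists at -0.61 and all genes at -0.06. Of 10000 matched sets, 0% lay as low as the lists. That share cannot decide on gene length, since matched genes were drawn singly while list members moved together (estimated correlation 0.733 and 0.732). A bias by gene length therefore stays open. WT pool 1 may account for the ribosomal list, whose mean was -0.10 without it and which was then not called. For oxidative phosphorylation the mean without it was -0.20, called with the preset but not with an estimated correlation, so that pool 1 and genotype cannot be told apart. An effect of Notch2 loss stays open and untested.

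Genes with a small p lay near Notch2, where 11 of 324 genes within 10 Mb had an unadjusted p under 0.01 (7 lower). Only genes with a mean log2 CPM of at least 0 were counted, in windows of at least 50 genes. Among the 11 was Gm42819, which lies within Notch2 and whose reads cannot always be told from those of Notch2. A share as high (3.40%, median window 0.571%) was found in 1.16% of 16528 windows of this width. The windows were centred on single genes and overlap, so they are not independent and that percentage may come from few loci. Without the S100a family, whose members can share reads, 8 of 315 genes remained at that p and 2.08% of windows were as high. Other genes noticed first, and Gm42819, remained in that count. Reads shared within the family cannot account for these 8 genes outside it, but stay open for the S100a genes. A segment of another strain carried along with the floxed allele is a candidate explanation. Without the 7 genes noticed first 13.4% of windows were as high. These genes were left out of this window while other windows kept theirs, which lowers its share by design. The 13.4% can therefore not decide between such a segment and a choice of genes by their values. An effect of Notch2 loss on its neighbours stays open and untested.

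Xist, expressed from the inactive X chromosome of females, was at 467, 316 and 0.265 CPM in WT pools 1, 2 and 3 and at 714, 0.224 and 520 CPM in CKO pools 1, 2 and 3. The sum of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 0.297, 153 and 269 CPM and 0.246, 327 and 70.8 CPM in the same order. CKO pool 2 had the highest share of reads outside annotated genes (35.3%) and the most genes detected (38187).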
